A study of Arabidopsis thaliana with 6 samples.

How the data were processed

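RNA from shoots of 3-week-old Arabidopsis thaliana seedlings (Col-0 background) was sequenced in 6 libraries, 3 of wild type and 3 of sme1-1, which the labels of the mutant samples write smeb-1. Per the labels' protocols the libraries were made with a stranded mRNA kit and read as 150 bp paired ends. The deposited values are TPM, a measure scaled to the same total in every library, per gene and per transcript, and the submitters' processing notes name STAR 2.5.2b and kallisto 0.43.0 without saying which step each did. The authors also deposited the transcript annotation, whose source column names Araport11 for 59448 transcripts and scallop, a transcript assembler, for 16761. There are 37869 genes and 76209 transcripts, and the TPM of each of the 37869 genes equalled the sum of its transcripts within 0.01 TPM. Every library sums to 1000000 TPM. TPM keep no depth, so the depth per library is unknown and no interval or detection floor is given. A value of 0 is described only as listed at 0.

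Gene symbols and products came from the RefSeq annotation of TAIR10.1, in which 37573 of the 37869 gene identifiers were found. The deposited annotation names no genome build; its last exon on each of the 5 nuclear chromosomes ends inside the TAIR10.1 sequence, and 99.44% of its 141522 nuclear introns begin with GT or GC and end with AG on that sequence. Intron positions are printed as deposited and gene positions as in RefSeq, both counted from 1.

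The comparison was sme1 against wild type with all 6 libraries and no covariate. Gene levels were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend) on log2(TPM + 1) for the 20100 genes with a mean of at least 1 TPM, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is on the log2(TPM + 1) scale, which understates the change of low genes. Transcript usage was tested with limma diffSplice (Simes p per gene) on log2(TPM + 1) of transcripts with a mean of at least 1 TPM in genes with 2 or more of them. Splicing events were built from the deposited annotation: a retained intron is an intron of 1 transcript that lies wholly inside an exon of another transcript of the gene, an alternative 5' or 3' splice site is a pair of introns that share the other end and whose differing ends lie in 1 exon (the tested site is that of the shorter intron), and a skipped exon is an internal exon with its 2 flanking introns against the intron that joins the same outer sites. Per library the TPM of transcripts with the event (R) and of those with the stated alternative (S) were summed. For retention S holds only transcripts that splice out exactly that intron, and for alternative sites only those with exactly the longer intron. Other transcripts of the gene are in neither sum, so a share R/(R + S) is not a share of the gene. Limma was run on log2((R + 0.1)/(S + 0.1)). Events needed a mean R + S of at least 2 TPM and a mean share R/(R + S) between 0.02 and 0.98. These shares rest on the apportioning of reads to transcripts that the deposited TPM carry and are not counts of reads across junctions. The median retained share per library was compared by an exact two-sided permutation test of means over the 20 assignments of 3 and 3 libraries. Overlaps were tested with Fisher's exact test over genes tested in both ways.

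The 14 gene lists, with 308 members in all, were written from memory and matched by locus, and no member was dropped. These lists, the tests above, except the overlaps split by direction, and the rule for named genes were fixed before the data were examined. They were tested with camera (limma) with a preset correlation of 0.01, with camera with an estimated correlation and with fry, and adjusted over the lists. None of the calls that camera made with the preset correlation held with an estimated correlation. Root and floral organ markers stand for tissue that a shoot sample could hold besides leaves and stem. The rule named SME1 and SmE-a; the 10 largest rises and 10 largest falls among genes past the threshold whose libraries do not overlap between genotypes and whose higher group has a mean of at least 5 TPM, and up to 4 members of each list with the smallest adjusted p. For splicing it named the 10 introns with the largest rise and the 5 with the largest fall in retention, the 3 largest changes of each other class of event, and up to 4 members of each list with a changed intron or changed usage, with at most 1 intron per gene. The following were named after their values were seen: NPR1, GSTF8, FER1, ZAT12, ZAT10, CAT1, CAT2, CAT3 (main transcript), GPX1 (gene level), GSH2, HSFA7A, RBCS1A, RBCS1B, CCA1, LHY, PRR9, TOC1, LUX and ELF4 (gene level), FT and LSM1A, the genes given for usage, which were picked among the list members the rule allows as those past both usage tests, and every gene named under other observations. The 4 further gene lists (iron deficiency, ferritins, sugar starvation, abundant root genes) and the 14 families taken by keyword from RefSeq product names were chosen after results were seen, and the 4 members of each family with the smallest adjusted p were looked at.

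Alternatives fixed at the same time as the tests were leaving out each library, the replicate number as a block, median-of-ratios scaling, quantile normalization, limma without a trend, a pseudocount of 0.1 for genes and transcripts and 0.5 for events, other filters on low values, a 2-fold threshold, a change in share of at least 10 points, an F test for usage, retaining transcripts with at least 1 spliced intron, and other forms of the list tests. Alternatives added later were a share test for usage (limma on log2 of a transcript over the rest of its gene), events from Araport11 transcripts alone, a minimum of 2 TPM per event in each genotype and the overlaps split by direction, with all of their alternatives.

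Each test was tried on simulated data: each feature was drawn around its mean with its spread within genotypes and no difference between them, and 200 features were then multiplied by a known factor in the sme1 libraries. The gene test recovered 40.0% of genes changed 1.5-fold, 67.7% of those changed 2-fold and 92.4% of those changed 4-fold, with 8 false calls among 19844 genes. The retention test recovered 0 of 57 introns whose ratio changed 2-fold, 37.7% of those changed 4-fold and 71.9% of those changed 8-fold, with 6 false calls among 15831 introns. diffSplice recovered 38.5%, 87.0% and 100.0% of genes with a transcript changed 2-, 4- and 8-fold with 79 false calls among 9328 genes, and the share test 4.6%, 49.3% and 89.4% with 3. R and S of an intron were drawn separately. Far more features were called in the real data, where the adjusted threshold is less strict, so these rates do not measure recovery there. Splice site scores, GC content and length of introns came from the TAIR10.1 sequence, and their medians were compared by permutation tests with 100000 resamples within 10 classes of expression. Site scores sum log2 odds over 9 bases at the 5' site (3 of them exonic) and 15 bases at the 3' site and were had for 99.51% of tested introns. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the events and permutation tests. Reads of near-identical copies (the LHCB1, RBCS, KIN and CBF genes) can be split between copies in the deposited values, so their single values are uncertain.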

Results

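RNA was sequenced from shoots of 3-week-old Arabidopsis thaliana Col-0 seedlings grown in vitro under control conditions in long days. The series sets sme1-1, a mutant of SME1 (SmE-b, AT2G18740), against wild type, with 3 libraries of each genotype. SME1 encodes SmE, a core protein of the ring that spliceosomal small nuclear ribonucleoproteins carry. The series title ties loss of SME1 to tolerance of oxidative stress, so the comparison asks how the mutant shoot transcriptome differs before any stress is given. Each library was deposited as TPM per gene and per transcript and sums to 1000000 TPM, so the sequencing depth behind a value is unknown. The labels do not say whether the 3 libraries of a genotype come from separately grown plants, and p-values here measure only the spread between these libraries, which may be technical. The hour of harvest is not given in the sources used here.

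The libraries of a genotype resembled each other. Across genes, which are not independent replicates, log2 values correlated at 0.985 or more within wild type, at 0.982 or more within sme1 and between 0.855 and 0.904 across genotypes, and the first principal component, with 87.8% of the variance, separated the genotypes. Wild-type libraries had between 18827 and 18997 genes at 1 TPM or more, and sme1 libraries between 20344 and 20580. The 20 most abundant genes took 16.0% to 16.7% of all TPM in wild type and 13.0% to 14.4% in sme1.

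SME1 fell in sme1. Its mean was 75.4 ± 1.496 TPM in wild type and 32.5 ± 3.28 TPM in sme1 (SD, n = 3 each), a log2 change of -1.19 with a standard error of 0.08 (limma adjusted p = 4.36e-05). The single libraries held 76.9, 73.9 and 75.3 TPM in wild type and 36.1, 31.6 and 29.7 TPM in sme1, so none went against its label. The main transcript, AT2G18740.1, went from 71.9 ± 2.04 to 19.2 ± 2.84 TPM, while an assembled transcript of the same gene, TCONS_00018377, went from 0.461 ± 0.163 to 12.8 ± 2.95 TPM, and the gene passed the test of transcript usage (limma diffSplice adjusted p = 1.01e-08). The gene lies on chromosome 2 between 8123195 and 8125078 in the RefSeq annotation of TAIR10.1. SmE-a (AT4G30330), the second gene for the same protein, rose from 23.8 ± 2.45 to 33.6 ± 1.14 TPM, a log2 change of 0.49 (limma adjusted p = 0.00183). This was 0.26 after median-of-ratios scaling (limma adjusted p = 0.0432).

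**Figure D1:**
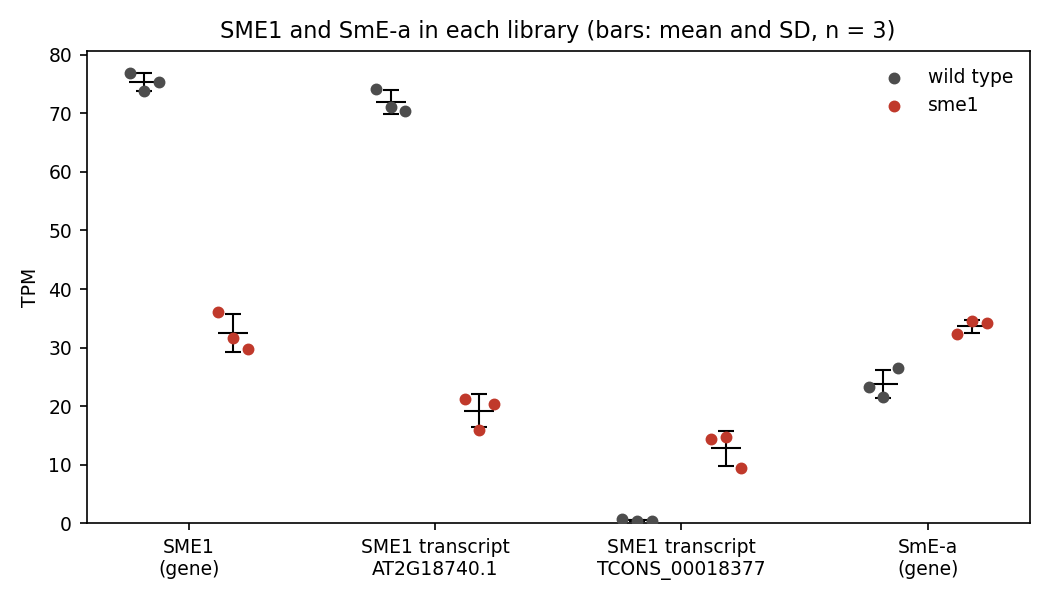
TPM of SME1, of 2 of its transcripts and of SmE-a in each library; points are the 3 libraries of a genotype, bars the mean and SD. SME1 lay between 73.9 and 76.9 TPM in wild type and between 29.7 and 36.1 TPM in sme1, and SmE-a was higher in each sme1 library than in each wild-type library.

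Of 20100 genes with a mean of at least 1 TPM, 13529 changed between the genotypes (limma, adjusted p under 0.05), 9505 higher and 4024 lower in sme1. Of these, 2830 were higher and 952 lower by at least 2-fold. The median gene was higher by 0.22 on the log2 scale, and scaling to the median gene moved the split to 6813 higher and 6674 lower (50.5% higher, against 70.3% on the deposited values), while quantile normalization gave 6218 higher and 7201 lower. After median-of-ratios scaling 10837 of the genes were called in the same direction as on the deposited values and none in the opposite direction; after quantile normalization 64 were opposite. Medians of gene lists are therefore given relative to the median gene as well.

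Of the 10 genes picked as largest rises by the rule fixed beforehand, AT1G13609, a defensin-like gene, rose most on the log2(TPM + 1) scale (7.63). Its mean went from 5.67 ± 2.88 to 1319 ± 649 TPM. The transcription factor genes bHLH38 (0.415 ± 0.173 to 260.7 ± 146 TPM) and BHLH100 (0.453 ± 0.0865 to 204.7 ± 128 TPM), known from the response to low iron, rose by 7.40 and 6.98 on the log2 scale. AT1G47395 and AT1G47400, which encode the short IRONMAN peptides IMA2 and IMA1, rose from 1.49 ± 0.535 to 394.6 ± 168 TPM and from 0.792 ± 0.554 to 230.4 ± 123 TPM. The lipid transfer protein gene LTP3 rose from 1.15 ± 0.158 to 297.9 ± 79.7 TPM, the late embryogenesis abundant gene LEA7 from 0.170 ± 0.156 to 175.6 ± 119 TPM, the pathogenesis-related gene PR1 from 0.968 ± 1.21 to 214.7 ± 23.56 TPM and the non-coding AT2G00920 from 1.31 ± 0.464 to 292.9 ± 133 TPM. AT1G48750, another lipid-transfer family gene, was listed at 0 in all 3 wild-type libraries and at 210.1, 131.0 and 182.6 TPM in sme1. Limma adjusted p-values of these 10 genes lay between 4.93e-06 and 4.23e-05.

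Of the 10 genes picked as largest falls, DIN10, a dark-inducible raffinose synthase family gene, fell most, from 1338 ± 226 to 18.04 ± 11.4 TPM (log2 change -6.34). The dark-inducible SEN1 fell from 955.6 ± 212 to 29.2 ± 7.13 TPM (-5.00), the proline dehydrogenase gene ERD5 from 349.1 ± 151 to 10.4 ± 0.422 TPM (-4.85) and the monosaccharide transporter gene STP1 from 462.6 ± 43.1 to 31.7 ± 14.9 TPM (-3.95). The transcription factor gene WRI4 fell from 147.4 ± 9.13 to 7.83 ± 1.89 TPM, the DnaJ-domain gene AT1G72416 from 468.5 ± 97.4 to 27.6 ± 18.4 TPM. The BTB/POZ gene AT2G30600 fell from 384.6 ± 56.6 to 24.0 ± 4.09 TPM, the protein kinase gene AT3G59350 from 260.9 ± 26.6 to 17.39 ± 8.53 TPM and the non-coding AT5G03615 from 383.5 ± 154 to 5.69 ± 3.03 TPM. CML30, a calcium-binding EF-hand gene, was at 20.2, 15.2 and 12.6 TPM in wild type and listed at 0 in all 3 sme1 libraries. Limma adjusted p-values of these 10 genes lay between 1.63e-05 and 0.000348.

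**Figure D2:**
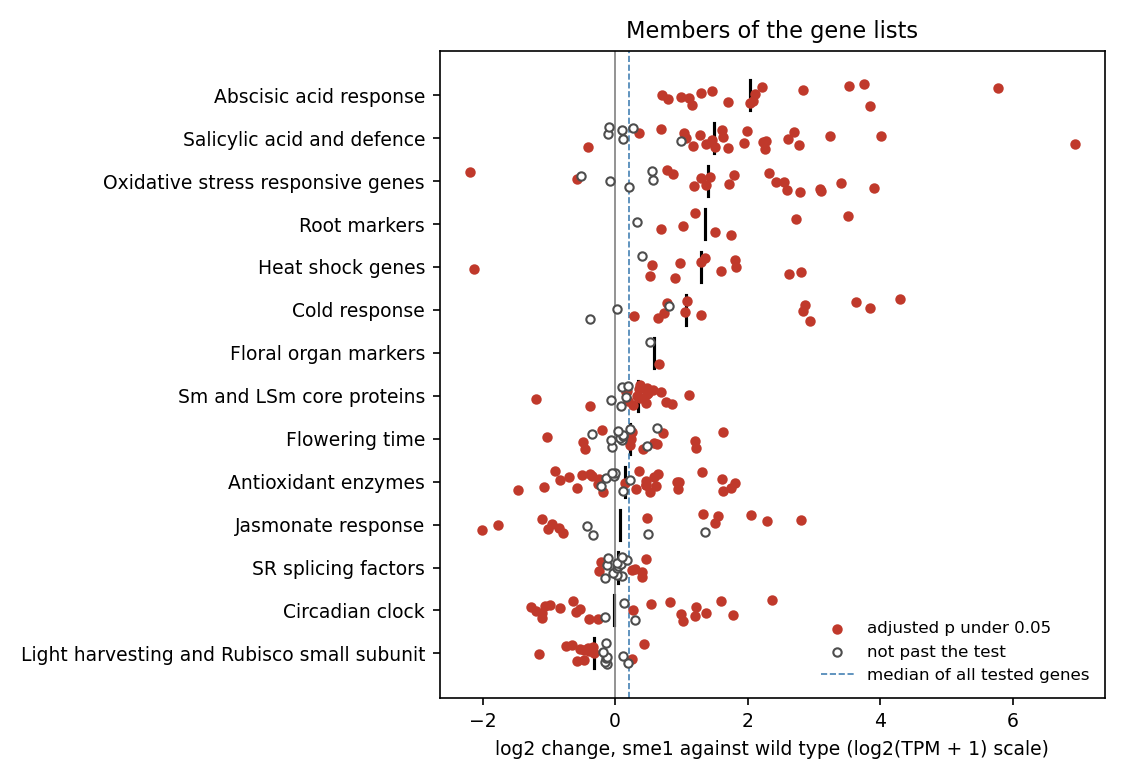
Log2 change (sme1 against wild type, on the log2(TPM + 1) scale) of each tested member of the 14 gene lists; filled points passed the gene test, the black line is the list's median and the dashed line the median of all tested genes, 0.22. Medians run from -0.31 for light harvesting and Rubisco small subunit genes to 2.04 for abscisic acid response genes.

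Abscisic acid response genes rose without exception among those tested. All 17 rose, with a median log2 change of 2.04 (1.83 relative to the median gene). Among them were the dehydration gene RD22 (55.2 ± 4.83 to 403.6 ± 80.2 TPM), the transcription factor gene ABF2 (10.01 ± 0.0574 to 44.7 ± 6.43 TPM) and the phosphatase genes HAB2 (22.1 ± 0.357 to 50.9 ± 3.40 TPM) and HAI2 (0.475 ± 0.0450 to 21.0 ± 7.33 TPM). Of 16 cold response genes 13 rose and none fell (12 and 2 after median-of-ratios scaling), with a median of 1.07 (0.86 relative). RD29A rose from 15.66 ± 2.03 to 328.7 ± 65.01 TPM, COR15A from 212.5 ± 22.3 to 1529 ± 162 TPM, GOLS3, for galactinol synthesis, from 0.858 ± 0.155 to 13.5 ± 2.66 TPM and KIN1 from 38.8 ± 5.40 to 499.5 ± 113 TPM; reads of KIN1 and KIN2, and of the CBF genes, may be shared between near-identical copies. Adjusted over the list alone the counts were the same, 17 and 13. Both lists passed camera with the preset correlation (limma adjusted p = 0.000105 and 0.00626) and neither did with an estimated correlation (adjusted p = 0.62 for each). Root marker genes rose in the same libraries, 7 of 8 tested with a median log2 change of 1.36.

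Defence genes tied to salicylic acid mostly rose, 23 of 30 against 1 that fell, NPR1 (27.7 ± 3.22 to 20.5 ± 1.35 TPM), with a median of 1.49 (1.27 relative). Besides PR1, the protease gene AED1 rose from 0.907 ± 0.224 to 11.4 ± 0.859 TPM, WRKY54 from 2.15 ± 0.0889 to 14.4 ± 2.497 TPM and the salicylic acid synthesis gene ICS1 from 8.91 ± 0.647 to 21.4 ± 0.440 TPM. Adjusted over the list alone the counts were again 23 and 1. The list passed camera (limma adjusted p = 0.00626), but not with an estimated correlation (adjusted p = 0.683). Jasmonate response genes went both ways, 7 higher and 7 lower of 18 tested, and the same adjusted over the list alone. LOX2, for jasmonate synthesis, rose from 48.8 ± 16.3 to 345.0 ± 107 TPM and the storage protein gene VSP1 from 5.02 ± 0.908 to 24.0 ± 5.11 TPM. The repressor genes JAZ9 and JAZ2 fell from 185.2 ± 34.1 to 45.1 ± 5.66 TPM and from 51.2 ± 7.13 to 28.0 ± 1.57 TPM. The list did not pass camera (limma adjusted p = 0.200, direction down), while its median, 0.07 (-0.15 relative), and mean, 0.26, were positive. The root markers rose beside both lists.

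Among genes that respond to oxidative stress 17 of 24 rose and 2 fell, with a median of 1.399 (1.18 relative), and the counts were the same adjusted over the list alone. The glucosyltransferase gene UGT74E2 rose from 0.434 ± 0.0723 to 7.68 ± 1.22 TPM, the mitochondrial NAD(P)H dehydrogenase gene NDB2 from 3.86 ± 0.422 to 23.3 ± 3.11 TPM. The alternative oxidase gene AOX1A rose from 24.2 ± 2.19 to 60.7 ± 4.24 TPM and the glutathione S-transferase gene GSTU7 from 7.43 ± 0.578 to 27.1 ± 4.62 TPM. The 2 that fell were GSTF8 (280.8 ± 19.5 to 190.4 ± 31.5 TPM) and the ferritin gene FER1 (348.2 ± 39.8 to 82.8 ± 39.6 TPM). Of the zinc finger genes, ZAT12 was at 11.2 ± 7.38 TPM in wild type and 14.5 ± 1.96 TPM in sme1 and ZAT10 at 27.0 ± 16.0 and 26.5 ± 4.85 TPM, short of the threshold. The list passed camera (limma adjusted p = 0.0205) but not without wild-type replicate 1 (adjusted p = 0.0558) or with an estimated correlation (adjusted p = 0.62). The root markers rose in these libraries too.

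Antioxidant enzyme genes divided, with 18 higher and 12 lower of 37 tested (15 and 17 after median-of-ratios scaling, 14 and 14 after quantile normalization), and the same adjusted over the list alone. Among those that rose were the glutathione reductase gene GR1 (37.4 ± 2.47 to 133.7 ± 9.93 TPM), the dehydroascorbate reductase gene DHAR2 (13.3 ± 0.457 to 47.4 ± 5.13 TPM), GPX6 (107.8 ± 5.71 to 332.4 ± 28.1 TPM) and the iron superoxide dismutase gene FSD3 (18.8 ± 1.26 to 48.1 ± 1.51 TPM). The catalase genes CAT1 (69.0 ± 1.44 to 24.9 ± 6.12 TPM) and CAT2 (404.3 ± 38.4 to 284.9 ± 24.4 TPM), GPX1 (967.4 ± 77.2 to 462.8 ± 52.7 TPM) and the glutathione synthesis gene GSH2 (120 ± 13.4 to 63.2 ± 2.01 TPM) fell. The main transcript of CAT3, the other catalase gene listed, did not fall. It was at 1250 ± 40.7 TPM in wild type and 1412 ± 306 TPM in sme1, above both other genes. The list did not pass camera (limma adjusted p = 0.649), whose direction was down while the list's median, 0.15, and mean, 0.22, were positive. Camera compares a list with the other genes, and relative to the median gene the list's median was -0.07.

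Heat shock genes rose in 11 of 13 cases and 1 fell, or 12 and 1 adjusted over the list alone, with a median of 1.304 (1.09 relative). HSFB1, for a heat shock factor, rose from 11.2 ± 0.302 to 42.3 ± 2.66 TPM, the small heat shock protein gene HSP17.6B from 1.83 ± 0.420 to 16.3 ± 1.48 TPM. The chaperone gene HSP70-4 rose from 2.92 ± 0.448 to 26.7 ± 4.91 TPM and the coactivator gene MBF1C from 7.23 ± 0.810 to 23.9 ± 1.70 TPM. HSFA7A fell from 13.7 ± 2.56 to 2.35 ± 0.487 TPM. The list passed camera (limma adjusted p = 0.0173) but not at a mean of at least 5 TPM (adjusted p = 0.053) or with an estimated correlation (adjusted p = 0.62). Root markers were higher in the same libraries.

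Photosynthetic antenna and Rubisco genes were mostly lower on the deposited values, but not after quantile normalization, where 6 rose and 6 fell. Of 21 genes for light harvesting proteins and the Rubisco small subunit 11 fell and 2 rose, RBCS1A (10340 ± 576.4 to 12380 ± 825.4 TPM) and RBCS1B (545.5 ± 40.3 to 744.8 ± 114.8 TPM), or 17 and none after median-of-ratios scaling, with a median of -0.31 (-0.53 relative). LHCB1.4 fell from 6807 ± 541 to 3098 ± 478 TPM, RBCS3B from 5980 ± 133 to 3606 ± 477 TPM. RBCS2B fell from 2394 ± 217 to 1519 ± 108 TPM and LHCA2 from 4524 ± 93.1 to 3142 ± 265 TPM, although LHCA2 lost its call after quantile normalization (log2 change -0.10, limma adjusted p = 0.140). The LHCB1 and RBCS genes are near-identical copies, so their single values are uncertain. Adjusted over the list alone the counts were 2 and 11, and the list passed camera (limma adjusted p = 0.000203) but not with an estimated correlation (adjusted p = 0.629). Root markers were higher in the same libraries.

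Clock genes moved in both directions, with 11 higher and 12 lower of 26 tested (12 and 12 adjusted over the list alone). LNK1 rose from 24.6 ± 1.68 to 131.7 ± 9.69 TPM, CDF1 from 18.9 ± 2.02 to 59.3 ± 5.88 TPM and RVE1 from 16.4 ± 0.615 to 39.4 ± 3.64 TPM, as did the morning genes CCA1 (41.2 ± 5.02 to 82.8 ± 8.02 TPM), LHY (19.8 ± 3.59 to 41.2 ± 6.20 TPM) and PRR9 (15.73 ± 5.38 to 54.9 ± 12.9 TPM). RVE4 fell from 198.6 ± 2.19 to 111.5 ± 1.03 TPM, and so did the evening genes TOC1 (25.8 ± 5.21 to 16.2 ± 1.96 TPM) and LUX (15.6 ± 3.82 to 6.62 ± 0.910 TPM), while the evening gene ELF4 rose (2.73 ± 0.809 to 7.66 ± 1.85 TPM). The list did not pass camera (limma adjusted p = 0.210), and its median of -0.01 (-0.23 relative) and mean of 0.14 differ in sign. Levels of clock genes depend on the hour of harvest, which is unknown for both genotypes, so these values do not separate genotype from hour.

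Of 25 flowering-time genes 10 rose and 4 fell (5 and 7 after median-of-ratios scaling, 6 and 7 after quantile normalization), or 10 and 3 adjusted over the list alone. FUL rose from 4.98 ± 1.08 to 17.3 ± 2.22 TPM, SPL9 from 3.81 ± 0.0499 to 10.11 ± 0.715 TPM, the chromatin factor gene FVE from 20.3 ± 0.290 to 32.0 ± 1.26 TPM and the florigen gene FT from 0.415 ± 0.0698 to 2.36 ± 0.822 TPM, while SPL5 fell from 5.14 ± 0.459 to 2.02 ± 0.156 TPM. The list did not pass camera (limma adjusted p = 0.884).

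Genes for Sm and LSm proteins, among them the partners of SmE in its ring, did not pass camera as a list (limma adjusted p = 0.0851). Of 24, 17 rose and 2 fell, SME1 itself and LSM1A (62.4 ± 4.62 to 48.0 ± 1.45 TPM), with a median of 0.35 (0.13 relative); the counts were the same adjusted over the list alone and 9 and 3 after median-of-ratios scaling (14 and 3 after quantile normalization). SmD1-a rose from 12.6 ± 1.295 to 28.3 ± 1.07 TPM, LSM3A from 30.2 ± 0.723 to 55.8 ± 4.43 TPM and SmD3-a from 20.8 ± 1.82 to 36.1 ± 1.62 TPM. Root markers were higher in the same libraries. Of 19 SR splicing factor genes 5 rose and 2 fell, also adjusted over the list alone, but 3 rose and 12 fell after median-of-ratios scaling and 3 rose and 6 fell after quantile normalization. RSZ22a rose from 30.1 ± 1.24 to 40.0 ± 1.46 TPM and SR30 from 73.9 ± 2.81 to 98.9 ± 8.65 TPM. SCL30A (31.6 ± 1.60 to 39.3 ± 1.94 TPM) lost its call after median-of-ratios scaling (log2 change 0.07), and SCL28 (0.922 ± 0.154 to 1.64 ± 0.0474 TPM) changed sign after quantile normalization (-0.05, limma adjusted p = 0.70). The SR list did not pass camera (limma adjusted p = 0.649, direction down), with a median of 0.04 (-0.18 relative) and a mean of 0.08.

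Markers of organs that a shoot sample should lack or hold little of were measured as well. Of 8 tested root markers 7 rose (6 after median-of-ratios scaling and 5 after quantile normalization, none lower), also 7 adjusted over the list alone, and all stayed low in absolute terms. The iron transporter gene IRT1 rose from 0.645 ± 0.381 to 18.03 ± 5.98 TPM, the root hair genes PRP3 from 0.169 ± 0.0609 to 7.11 ± 2.95 TPM and EXPA7 from 0.124 ± 0.0976 to 2.92 ± 1.33 TPM, and the NADPH oxidase gene RHD2 from 0.387 ± 0.121 to 2.26 ± 0.686 TPM. The list's median was 1.36 (1.15 relative), and it did not pass camera (limma adjusted p = 0.071; 0.0414 without sme1 replicate 2). Of the 2 floral organ genes tested, SEP3 rose from 0.763 ± 0.320 to 1.79 ± 0.405 TPM, a call lost without sme1 replicate 3 (limma adjusted p = 0.0507) and after quantile normalization (0.486), and PI was at 1.56 ± 0.729 and 2.64 ± 0.706 TPM (limma adjusted p = 0.0878). That list did not pass camera (limma adjusted p = 0.649).

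Transcripts of the same gene differed in their log2 change in 2176 of 9382 genes with at least 2 expressed transcripts (limma diffSplice, adjusted p under 0.05), or 23.2%. This does not test each transcript's share of its gene. A share test with a separate spread for each transcript, added after seeing the data because diffSplice made 79 false calls in 9328 simulated genes against 3 for the share test, called 348 genes, of which 328 were among the 2176. Apart from the moved transcripts, the simulation held no difference in gene level, while most real genes changed level. A change of level alone can move low and high transcripts unequally on the log2(TPM + 1) scale. The 79 therefore do not measure false calls among the 2176. Besides SME1, the members of the fixed lists looked at that passed both tests were SR30, RS2Z33, PRR7, LUX, FLK, ABF4, RD29B and LHCB2.1. In SR30 the transcript AT1G09140.1 rose from 12.8 ± 2.03 to 39.0 ± 2.93 TPM while AT1G09140.2 went from 58.0 ± 2.91 to 53.6 ± 6.39 TPM. In RS2Z33 the transcript AT2G37340.6 went from 4.60 ± 0.855 to 0.0912 ± 0.0956 TPM, and in the clock gene PRR7 AT5G02810.2 went from 9.51 ± 4.48 to 31.5 ± 4.30 TPM while the gene as a whole fell. In FLK, an RNA-binding activator of flowering, AT3G04610.1 went from 14.6 ± 2.31 to 8.61 ± 0.539 TPM and AT3G04610.2 from 6.25 ± 0.698 to 13.8 ± 0.460 TPM, and in ABF4 AT3G19290.5 went from 2.49 ± 0.348 to 12.9 ± 1.86 TPM. Without sme1 replicate 2 the count was 1345 and without sme1 replicate 3 it was 1326.

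Intron retention was higher in sme1 across many introns. The median retained share over 16035 introns of 8028 genes was 16.2 ± 0.865% in wild type and 18.8 ± 1.03% in sme1 (SD, n = 3), with single libraries between 15.2% and 16.8% and between 17.78% and 19.85%; the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Of the tested introns 64.7% were higher in sme1, and 683 introns of 527 genes changed (limma, adjusted p under 0.05), 548 higher and 135 lower. The calls of single introns were fragile. With any 1 library left out between 12 (without sme1 replicate 1) and 125 (without wild-type replicate 3) introns passed, and with Araport11 transcripts alone 51 did, 27 higher and 24 lower. In the fits without 1 library between 61.5% and 65.6% of all tested introns were higher.

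Among the largest rises in retention were introns of BT4 and AT2G38780. The retained share of the BT4 intron on chromosome 5 from 26932524 to 26933114 (positions as deposited) went from 17.35 ± 4.79% to 80.8 ± 4.62%, and that of an intron of AT2G38780 from 27.7 ± 6.54% to 80.7 ± 4.62%. Introns of ZFN3 (46.0 ± 15.3% to 100.0%), SAMTL (34.5 ± 4.98% to 93.9 ± 10.5%), AT3G50790 (32.4 ± 18.4% to 90.7 ± 8.14%), AT3G22220 (33.2 ± 14.2% to 83.2 ± 5.87%) and AT3G48820 (28.3 ± 1.68% to 77.8 ± 8.94%) also rose. AT4G08093, AT2G14230 and CYP722A1 completed the 10, with wild-type SDs of 32.1, 27.2 and 8.93 points that exceeded their wild-type means. The retained share fell in ABCB4, an auxin transporter gene (64.7 ± 2.79% to 17.0 ± 1.67%), in AT3G51330 (94.9 ± 2.06% to 46.1 ± 11.6%), AT3G27025 (89.5 ± 9.08% to 38.0 ± 2.78%) and the chloroplast protease gene CLPP6 (70.5 ± 13.6% to 20.2 ± 7.02%). For AT1G66880, the fifth by the rule, 2 wild-type libraries list the event at 0 TPM, so its wild-type share rests on 1 library and no change is given. Without single libraries BT4 and ABCB4 kept their calls in 4 of 6 fits each, ZFN3 in 3 and AT2G38780 and AT3G51330 in 2. AT3G50790, AT4G08093, AT2G14230, CYP722A1, AT3G27025 and AT1G66880 kept theirs in 1 fit each, and SAMTL, AT3G22220, AT3G48820 and CLPP6 in none. Event means were low, from 2.25 TPM (SAMTL) to 5.24 TPM (ABCB4) except for AT2G38780 (10.7 TPM), against a filter of 2 TPM.

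Members of the fixed lists with a changed intron were almost all higher in retention. The share rose in CCA1 from 50.4 ± 1.84% to 80.1 ± 4.72%, in LUX from 68.5 ± 11.5% to 94.2 ± 3.03%, in FLK from 21.97 ± 2.91% to 40.6 ± 1.81%, in MAF4 from 4.65 ± 4.98% to 38.5 ± 5.63% and in SOC1 from 1.203 ± 0.274% to 3.53 ± 0.662%. Among antioxidant genes it rose in GPX1 from 13.1 ± 1.01% to 29.5 ± 4.65% and in MDAR6 from 33.4 ± 13.9% to 76.9 ± 6.40%. It rose also in SR30 (5.03 ± 0.235% to 10.7 ± 1.18%), RD26 (65.7 ± 7.33% to 88.1 ± 3.60%), PBS3 (60.4 ± 35.3% to 88.8 ± 3.42%) and JAZ10 (1.44 ± 1.28% to 7.12 ± 3.40%), and fell in PI (52.5 ± 11.4% to 6.01 ± 6.66%). In RD29B the tested ratio fell while the share itself went from 0 to 4.63%, so no direction is given. Limma adjusted p-values of these 13 introns lay between 0.0275 and 0.0499. Apart from MAF4 and PBS3, which each kept the call in 1 fit, none of them kept it when any 1 library was left out. These shares exclude transcripts that neither retain nor splice out exactly that intron, so they are not shares of the gene. In CCA1 the excluded AT2G46830.1 was at 26.6 TPM in wild type and 56.51 TPM in sme1, against an event mean of 20.48 TPM. In GPX1 AT2G25080.1 was at 915.9 and 443.8 TPM, against 31.28 TPM. In MDAR6 AT1G63940.1 was at 20.22 and 42.73 TPM, against 3.222 TPM. In SOC1 the event mean was 149.6 TPM, near the gene's 158.8 and 152.9 TPM.

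**Figure D3:**
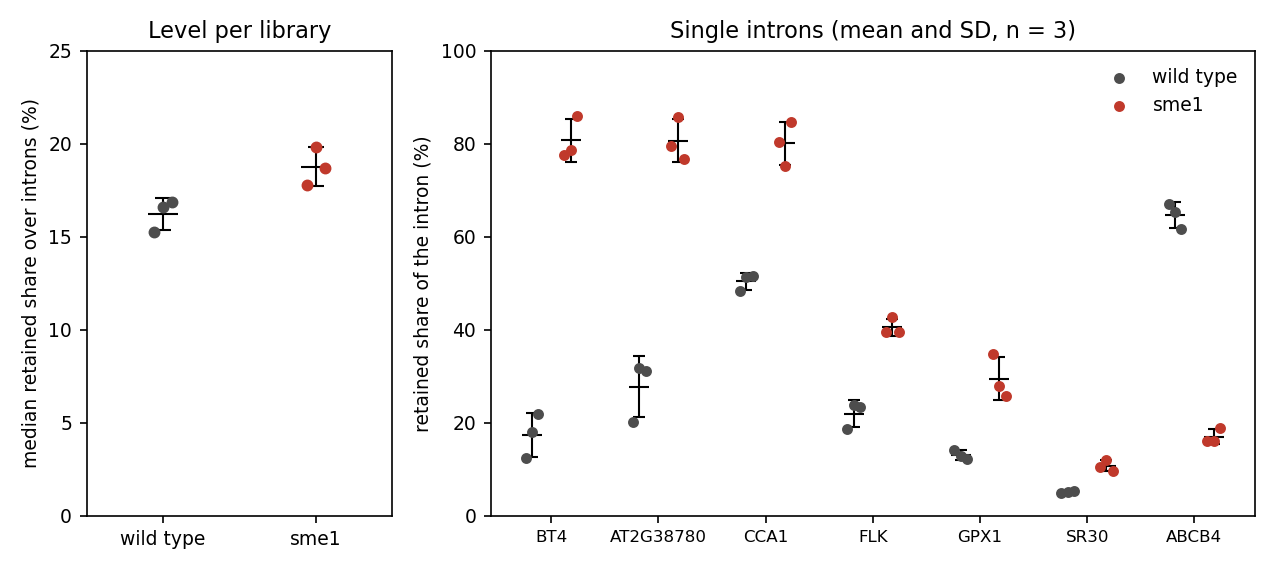
Left, the median retained share over 16035 introns in each library; right, the retained share of 7 introns in each library, with mean and SD (n = 3). The 3 sme1 libraries lie between 17.78% and 19.85% and the 3 wild-type libraries between 15.2% and 16.8%. A share leaves out transcripts of the gene that neither retain nor splice out exactly that intron.

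Other classes of splicing event gave fewer calls. Of 2959 alternative 5' splice sites 40 changed (limma, adjusted p under 0.05), 20 with more and 20 with less use of the tested site, of 5047 alternative 3' splice sites 20 changed, 8 more and 12 less, and of 905 exons 6 changed, all towards skipping. In the ubiquitin-conjugating enzyme gene UBC34 the share of one 3' site went from 4.71 ± 4.74% to 94.7 ± 8.70%, in the ferric reductase gene FRO3 from 74.4 ± 4.05% to 41.7 ± 1.23% and in AT2G38780 from 48.1 ± 6.60% to 9.75 ± 0.0766%. Inclusion of an exon fell in KAT5, for peroxisomal thiolase (90.8 ± 4.82% to 49.1 ± 8.95%), in AT2G38780 (47.9 ± 6.40% to 8.54 ± 1.26%) and in CYP76C6 (49.4 ± 4.74% to 3.84 ± 6.65%). The retained intron, 3' site and exon of AT2G38780 lie at the same place and share AT2G38780.6 and TCONS_00017991, so they are not separate changes. The share of one 5' site of LPP3 rose from 18.4 ± 2.40% to 75.1 ± 22.4%; the other 5' sites with the largest changes, in AT1G02475 and AT4G08869, are each at 0 TPM in 2 of the 3 wild-type libraries, so their wild-type share rests on 1 library. Leaving out 1 library gave between 0 and 8 changed 5' sites, 0 and 18 3' sites and 0 and 9 exons. The UBC34 share sets AT1G17280.7 against AT1G17280.2 alone and is not a share of the gene. Event means were near the filter of 2 TPM for UBC34 (2.498 TPM), LPP3 (2.773 TPM) and CYP76C6 (2.164 TPM). Those of FRO3, KAT5 and AT2G38780 lay between 18.84 and 34.25 TPM. In such fits UBC34 kept its call in 2 of 5 and the AT2G38780 exon in 3 of 6. The AT2G38780 3' site, KAT5 and CYP76C6 kept theirs in 1 fit each, LPP3, FRO3, AT1G02475 and AT4G08869 in none.

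Changes of retention and of gene level met in part in the same genes. Of 527 genes with a changed intron 393 (74.6%) also changed in level, against 68.3% of the other genes tested for both (odds ratio 1.36, Fisher's exact test, two-sided p = 0.00256). Genes with an intron of higher retention were more often lower in level, 169 of 419 (40.3%) against 25.1% of the others (odds ratio 2.02, two-sided exact p = 4.24e-11; 1.51 after median-of-ratios scaling, p = 4.71e-05). Of the list members given above with higher retention, GPX1, LUX and JAZ10 were lower in level. CCA1, MDAR6, RD26, PBS3, SR30 and FLK were higher in level instead. A fall of the spliced transcripts alone raises the tested ratio and lowers the gene's TPM, so these measures are not independent. With 1 library left out the first odds ratio passed only without wild-type replicate 3 (1.60, exact p = 0.0328) and the second in none of the 6 fits, where it lay between 0.718 (without sme1 replicate 2) and 2.61 (without sme1 replicate 3), on between 12 and 125 changed introns.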

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

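The share test for usage, the events from Araport11 transcripts alone, the minimum of 2 TPM per event in each genotype and the overlaps split by direction were chosen after results were seen. Except where a construction is given, the cause was not tested.

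Gene-level results kept their direction and their side of the threshold under most alternatives. The count of changed genes lay between 11938 and 12903 without any 1 library and between 10576 (mean of at least 5 TPM) and 15177 (no filter) under the other settings without a fold threshold; a 2-fold threshold, which by construction removes small changes, left 3782. Without single libraries the log2 change of SME1 lay between -1.27 and -1.13 and that of SmE-a between 0.42 and 0.56. Of the other genes named by the rule (those named after their values were seen are not counted), 918 comparisons stayed as reported, 4 lost and 3 gained a call and 1 changed sign: SCL28 with quantile normalization (-0.0492, limma adjusted p = 0.70). The 3 gained were all of PI. The direction of counts depends on scaling, as given in the report.

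Of the gene lists, 6 passed camera, and 5 to 7 did without any 1 library. With an estimated correlation camera passed 0 lists, and 0 had an unadjusted p under 0.05 (lowest 0.17); fry passed 12, 11 up and 1 down. Under fry the antioxidant enzymes (limma adjusted p = 0.000218) and the clock (limma adjusted p = 0.0288) went up where camera had them down, since fry, unlike camera, does not compare a list with the other genes.

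Changed usage was called in 1326 to 1911 genes without any 1 library, in 872 with transcripts of at least 5 TPM, in 3880 with no filter and in 348 with the share test, against 2176 reported. A pseudocount of 0.1 gave 1623 and an F test per gene 2108.

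Counts of splicing events moved under many settings. Against 683 introns, 12 to 125 passed without any 1 library, 1753 with a pseudocount of 0.5, 1181 with at least 10 TPM per event, 301 with no filter, 51 with Araport11 transcripts alone and 397 with a share change of at least 10 points, which by construction removes small changes. The count was 665 with retaining transcripts that have a spliced intron and 547 with at least 2 TPM in each genotype. The retention level kept its direction, with differences between 1.97 and 3.03 points without any 1 library, 2.32 for mean shares and 1.99 with at least 10 TPM per event. For 5' splice sites, 0 to 8 passed without any 1 library, 98 with a pseudocount of 0.5, 64 with at least 10 TPM and 16 with no filter. For 3' sites these were 0 to 18 without any 1 library and 51 with a pseudocount of 0.5, and for exons 0 to 9, 55 and, with at least 10 TPM, 36. The limma fits with a count of 0 had 452 (without sme1 replicate 1) and 422 (sme1 replicate 3) 5' sites, 618 (wild-type replicate 2) and 558 (sme1 replicate 2) 3' sites, and 156 and 128 (sme1 replicates 1 and 3) exons at an unadjusted p under 0.05. Of the comparisons of 37 named events 146 stayed as reported and 246 lost the call.

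The overlap of changed retention and changed level had odds ratios between 1.115 and 2.347 without any 1 library, and it missed the threshold (exact p between 0.228 and 0.80) except without wild-type replicate 3. Higher retention with lower level gave 0.7179 (without sme1 replicate 2, exact p = 1) to 2.607. Higher retention with higher level, 0.7028 in all libraries (exact p = 0.000799), gave 0.5407 to 1.599 and lay above 1 without wild-type replicate 2 (1.172), wild-type replicate 3 (1.106), sme1 replicate 1 (1.599) and sme1 replicate 2 (1.207). Fewer introns pass in each fit without 1 library. With median-of-ratios scaling and quantile normalization of the gene levels it missed the threshold (0.8411 and 0.9782, exact p = 0.135 and 0.869).

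With the replicate number as a replicate block limma called 13055 genes, 1977 genes for usage and 6 lists, with SME1 at -1.19 and SmE-a at 0.49. It called 0 introns, 0 5' sites, 0 3' sites and 0 exons, so none of the 37 named events, while 3796, 468, 622 and 161 had an unadjusted p under 0.05. Deviations of libraries with the same number correlated across genes at 0.0168, 0.0562 and 0.0322, each above any pair with different numbers (highest 0.00498) but below 0.1, so the numbers were not taken to pair the libraries. What depth limits was not tested, since depth is not known.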

Other observations

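The gene lists and families in this part, the test of the TPM scale, the test without the most abundant genes and the tests of iron and sugar genes were chosen after results were seen. The tests of root genes, of retention, of intron features and of intron number were set before their own results were seen.

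Of the 10 largest rises 4 were known iron deficiency genes. Of 18 tested members of a list of iron deficiency genes 17 rose and none fell, also after both other scalings, with a median log2 change of 2.92 (2.71 relative to the median gene). Besides the genes given in the report, bHLH101 rose from 2.88 ± 0.469 to 82.3 ± 26.7 TPM, IMA3 from 4.36 ± 0.766 to 178.1 ± 78.9 TPM, OPT3 from 10.61 ± 0.824 to 84.1 ± 33.5 TPM and BTS from 33.9 ± 1.93 to 131.2 ± 47.7 TPM, while FRO3 was not called and MYB72 was listed at 0 in wild type and not tested. The 3 ferritin genes for iron storage fell in every scaling (median -1.73), FER3 from 53.4 ± 4.93 to 27.9 ± 4.76 TPM and FER4 from 53.2 ± 5.46 to 16.35 ± 6.97 TPM. Camera adjusted p-values from limma were 1.38e-05 and 0.00906 for the lists, but 0.352 for both with an estimated correlation. Without the members among the 10 largest rises, the others still rose, by a median of 2.283 relative to the median gene (limma camera p = 0.000162, with an estimated correlation p = 0.293), so a low-iron response in sme1 shoots is a candidate explanation. Iron content was not analysed here. IRT1, FRO2, F6'H1, MYB10 and MYB72 are also known from roots, and root markers rose in the same libraries.

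Genes induced by sugar starvation or darkness fell. Of 19 tested members of such a list 17 fell and DIN2 rose (1.13 ± 0.447 to 52.7 ± 30.0 TPM), with a median of -1.70 (limma camera adjusted p = 4.6e-10, with an estimated correlation 0.182), and 18 fell after quantile normalization. ASN1 fell from 923.0 ± 25.6 to 94.1 ± 31.0 TPM and MCCA from 114.3 ± 29.9 to 17.65 ± 1.03 TPM. Without the members among the 10 largest falls the median of the others relative to the median gene was -1.758 (limma camera p = 4.11e-08, with an estimated correlation p = 0.0565), which is consistent with a weaker starvation response in sme1. Many such genes also follow the hour of day, and the hour of harvest is unknown, so a difference in harvest time stays open. Root markers rose in the same libraries.

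Families taken by product name, given as higher and lower of tested genes on the deposited values, stand here with limma camera adjusted p-values. More rises than falls in all 3 scalings were had by glutathione S-transferases (37 and 4 of 47, limma adjusted p = 0.00185), cytochromes P450 (86 and 14 of 120, limma adjusted p = 0.000925), lipid transfer proteins (42 and 7 of 56, limma adjusted p = 0.00481), class III peroxidases (30 and 3 of 42, limma adjusted p = 0.017), late embryogenesis abundant proteins (26 and 4 of 41, limma adjusted p = 0.0338), UDP-glycosyltransferases (59 and 12 of 86, limma adjusted p = 0.0487) and ribosomal proteins (259 and 30 of 352, limma adjusted p = 0.000327). So did WRKY factors (36 and 8 of 55, limma adjusted p = 0.101), expansins (13 and 3 of 21, limma adjusted p = 0.214) and aquaporins (12 and 5 of 25, limma adjusted p = 0.851). Even so 3 abundant aquaporin genes fell, PIP1;5 from 165.1 ± 4.87 to 34.2 ± 3.64 TPM, TIP2 from 848.4 ± 53.8 to 320.0 ± 6.40 TPM and PIP3 from 463.7 ± 36.1 to 185.3 ± 14.2 TPM. TIR-NBS-LRR disease resistance genes had more falls in all 3 (17 and 26 of 76, limma adjusted p = 0.00327), and histones too (12 and 13 of 45, limma adjusted p = 0.108). Counts turned with scaling for cysteine-rich receptor-like kinases (9 and 4 of 24, limma adjusted p = 0.412, with 8 and 9 after median-of-ratios scaling and 5 and 11 after quantile normalization) and pentatricopeptide repeat proteins (91 and 19 of 200, limma adjusted p = 0.412, with 18 and 93 after quantile normalization). With an estimated correlation no family passed (limma camera adjusted p from 0.608 to 0.952). GSTF12 rose from 4.53 ± 1.07 to 200.8 ± 80.2 TPM. Root markers rose beside these families.

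The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 split, the real one, gave as many calls: 13529 genes against at most 0 in the other splits, 2176 genes for usage against 5, 683 introns against 0, 40 alternative 5' sites against 0, 20 alternative 3' sites against 0 and 6 exons against 1.

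More genes were higher than lower in sme1, 70.3% of the changed genes. Without the 20 genes most abundant in wild type, and with the rest rescaled, 66.6% were still higher, which argues against these genes as the whole cause. Whether the TPM scale or a broad rise is behind the excess cannot be told apart: median-of-ratios scaling, with 50.5% higher, centres the genes by construction.

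Root marker genes rose in sme1 shoots. A second list of genes abundant in roots, sharing no gene with the fixed lists, rose as well, 8 of 11 tested and none lower, with a median 1.43 above the median gene (limma camera p = 0.039, with an estimated correlation p = 0.435). All 3 root beta-glucosidase genes were higher, BGLU23 from 153.0 ± 40.8 to 341.1 ± 114.9 TPM, BGLU21 from 1.61 ± 1.16 to 10.79 ± 6.30 TPM and BGLU22 from 1.58 ± 0.826 to 8.88 ± 3.63 TPM, and wild-type shoots also express BGLU23. TIP2-2 did not change (57.4 ± 2.74 and 59.1 ± 11.8 TPM). The beta-glucosidase genes are members of the second list, so the 2 tests are not separate. Both go with root tissue in the sme1 samples, and expression of root genes in the shoot stays open.

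Intron retention was higher in sme1. Genomic DNA would weigh most on weakly expressed genes. The median log2 change was 0.315 among the 5345 introns with the highest TPM and 0.229 among the 5345 with the lowest. This order is opposite to that prediction (difference 0.086, permutation p = 1e-05, the smallest possible). The p comes from resampling introns, which share transcripts and libraries, so it does not measure the spread between libraries. The added 0.1 TPM also shrinks changes at low TPM. Genomic DNA is therefore not decided. Among genes not past the gene test 79.2% of 159 changed introns were higher. A difference between whole libraries, such as in depth, would act on these genes too. Whether the higher number of detected genes in sme1 is the cause is therefore not decided. With Araport11 transcripts alone 52.9% of 51 changed introns were higher, while 62.3% of the 6814 tested introns were, so whether transcripts assembled from these reads add to the excess cannot be told apart on so few calls. A biological effect of sme1 on splicing stays open as a hypothesis.

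Features of the 547 introns with higher retention and known sites were set against the other 15409. Their 3' sites scored lower (medians 6.926 and 7.23, difference -0.304, permutation p = 0.0176, adjusted over 4 features 0.0351), so weaker 3' sites may make an intron more sensitive. This rests on calls that are fragile, with only 8 to 100 introns called higher when any 1 library is left out. For 5' sites (difference 0.205, permutation p = 0.20) and length (difference -7.0 bases, permutation p = 0.38) the medians went against the prediction of weaker sites and longer introns, short of the threshold, so both stay undecided. GC content was lower (difference -1.07 points, permutation p = 3e-05, adjusted 0.00012), against the prediction of higher GC.

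Protein-coding genes with introns rose slightly less than genes without (medians 0.21 and 0.28, difference -0.0688, permutation p = 1e-05, the smallest possible, over 16319 and 2404 genes). The difference met the prediction of a lower level of genes with introns. Genes with 1 intron had the highest median, 0.32. It was 0.25 with 2 to 4 introns, 0.18 with 5 to 9 and lowest, 0.17, with 10 or more. Splicing that limits the level of genes with many introns is a hypothesis, and that cause was not tested. The step from genes without introns (0.28) to genes with 1 intron (0.32) went the other way. Gene length and expression were not matched. Small nucleolar RNA genes had a median of 0.89 (58 higher and 11 lower of 152), or 0.72 after median-of-ratios scaling.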
